A study of Mus musculus with 7 samples.

How the data were processed

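Single-cell suspensions of fetal mouse lung were made into 10x Chromium 3' v3 libraries and sequenced on an Illumina NovaSeq6000, per the labels' protocols. The deposited files hold, for each library, a sparse matrix of raw UMI counts per gene and barcode with its gene and barcode lists, not normalised. Per the file headers, these counts were made with Cell Ranger 4.0.0 for the libraries with the shorter gene list (E10.5 A, E12.5 A and E14.5) and 6.0.0 for those with the longer one. The submitters' notes name Cell Ranger 6.6.0 instead, R 4.0.5, Seurat 4.3.0 and the build mm10. The files hold 26852 barcodes, none with under 500 UMIs, and no cell annotation was used here. Stage and replicate were taken from the labels. The letters A and B of E10.5 and E12.5 also separate 1 embryo from 3 pooled embryos and the shorter from the longer gene list, so they cannot be told apart from that batch. Each group has 1 or 2 libraries of separate embryos. Model p-values measure the spread between libraries, or around a line with 1 per stage. Fisher's test counts cells as units.

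Genes were matched between the lists by Ensembl identifier, which left 27040 genes with 99.4% to 99.8% of the UMIs (1227 of them have another symbol in the longer list). Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% mitochondrial UMIs, which between 44.7% (E10.5 A) and 90.7% (E10.5 B) of barcodes passed, 19089 in all. Scrublet, run per library through scanpy, marked 20 cells, which is too few to count as working, and these were removed. Doublets therefore remain, and removing the 5% of cells with the highest scores in each library was tried as an alternative. Median depth per cell used was 22130, 10785, 14379, 7744, 8580, 9865 and 7430 UMIs in the order E10.5 A, E10.5 B, E12.5 A, E12.5 B, E14.5, E16.5 and E18.5. As a check of the labels, Xist gave 1 to 28 UMIs per library and Ddx3y 814 to 3342.

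Cells were scaled to 10000 UMIs and log-transformed, and clustered with the Leiden method on 40 principal components of 3000 variable genes with 15 neighbours (resolution 1.5, seed 1). Mesenchymal cells were clustered again (2000 variable genes, resolution 0.75). No batch correction was made. Clusters were named "like" a type by fixed markers of 17 classes, with at least 3 markers up 2-fold at 10 CPM or more and a score of at least 1.5, and a cluster that failed this or whose leading genes spoke for another class stayed unnamed. A cluster of 194 cells led by Ager and Hopx, all from E18.5, was left out of epithelium in this way, since Msln, a mesothelial marker, was among its leading genes and no epithelial marker was. For clusters of low depth, 1 marker among the leading genes was asked for. The marker lists, gene lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. The mesenchymal resolution and the rule for low-depth clusters were set after cell numbers and clusters, but no gene results, had been seen. A resolution of 1.5 had been tried first, and it parted pericytes from vascular smooth muscle but left too few libraries with enough cells. Names are rebuilt from markers, and the perivascular class here includes vascular smooth muscle.

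Raw counts were summed per library and class where a library had at least 20 cells of it. The sums held 456108 to 2842726 UMIs in perivascular cells, 2864003 to 41276948 in mesenchyme, 172134 to 4908268 in endothelium and 1441939 to 7148060 in epithelium, so that E12.5 A endothelium and E12.5 B perivascular cells had the fewest UMIs. Blood endothelium had been planned, but no cluster was named lymphatic, so the endothelial class holds all endothelial-like cells. Genes with low counts were removed by filterByExpr, libraries were scaled by TMM, and edgeR 4.0.16 fitted quasi-likelihood models with embryonic day as a number (trends), with stage (E12.5 against E10.5) or, for perivascular against other mesenchyme, with library as a block and class by day as the tested term. Tests were two-sided, with Benjamini-Hochberg adjusted p under 0.05 as the threshold. The standard error of a log2 change is the change divided by the square root of F. A slope of a gene with 0 counts in a library rests in part on the small count that edgeR adds, and CPM values are TMM-normalised. Over the 6 comparisons across genes, adjustment was made within each. Shares have exact (Clopper-Pearson) 95% intervals, and a share of 0 an upper limit of 3 counts. The relation of share to day was tested by exact permutation.

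Named genes are the 6 rising and 6 falling genes with the largest change in perivascular cells and the 4 and 4 in the other comparisons (average log2 CPM of at least 5, predicted genes passed over), up to 4 genes of each list by p, and 19 mesenchymal genes in any case. Not every gene this rule takes is reported here. The 29 gene lists, each with at least 3 members tested, cover pericytes, contractile smooth muscle, fibrillar collagen and elastic matrix, basement membrane, cell cycle, Hedgehog, Wnt, BMP and TGF-beta, Notch, vascular growth and retinoic acid signalling, lung mesenchyme transcription factors, imprinted and fetal growth genes, glycolysis and hypoxia, oxidative phosphorylation, DNA methylation and early chromatin, myofibroblasts and lipofibroblasts, alveolar, distal tip and proximal airway epithelium, capillary endothelium, dissociation stress, interferon response, and markers of erythroid, epithelial, endothelial, mesothelial and leukocyte cells and of sex. Lists were tested with camera of limma 3.58.1 (preset correlation 0.01) and again with the correlation estimated, which from few libraries is itself uncertain. Barx1, Nkx6-1, Isl1 and Wnt2 in E10.5 cells were examined outside this rule. Gene positions come from GENCODE M21, which gave one for all 308 named genes.

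The alternatives were DESeq2 1.42.0 (test, and its size factors in edgeR), no count filter, a stricter cell filter (1000 genes, 5% mitochondrial UMIs), doublets kept, haemoglobin genes left out, the gene list as a covariate, other clustering resolutions, a minimum of 10 cells, each library left out in turn, and the letters A and B as a block. The procedures were tested on simulated counts drawn from these libraries. Of genes changed by 0.25 and 0.5 log2 per day, the perivascular trend recovered 12.1% and 76%, whole mesenchyme 76% and 100%, endothelium 78% and 100%, epithelium 58% and 100%, and the comparison of trends 23% and 86%. E12.5 against E10.5 recovered 37% of genes changed by 1 log2 and 98% of those changed by 2. Between 2 and 9 unchanged genes were called per comparison. Software was Python 3.11.15 with scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0 and matplotlib 3.10.9, and R 4.3.3.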

Results

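Fetal mouse lungs were profiled by droplet-based single-cell RNA sequencing (10x Chromium, 3' end counting with unique molecular identifiers, UMIs) at 5 stages from E10.5 to E18.5, in days of embryonic development. All animals were wild-type males. E10.5 and E12.5 had 2 libraries each, library A from 1 embryo and library B from 3 pooled embryos. E14.5, E16.5 and E18.5 had 1 library each, from 1 embryo, so these stages had no replicate spread of their own. The series was made to follow how pericytes of the lung develop. Pericytes are the mural cells that wrap capillaries, and with vascular smooth muscle they make up the perivascular cells. The 7 libraries held 26852 barcodes and 246940177 UMIs. The total was 18280636 and 24326430 UMIs for E10.5 A and B, 35422822 and 49417163 for E12.5 A and B, 57350946 for E14.5, 43844089 for E16.5 and 18298091 for E18.5. After filtering, 19069 cells were used. These were 538 and 1874 cells at E10.5, 1849 and 4833 at E12.5, 5200 at E14.5, 3118 at E16.5 and 1657 at E18.5. The median depth per cell used lay between 7430 UMIs at E18.5 and 22130 in E10.5 A. Libraries E10.5 A, E12.5 A and E14.5 had been counted against a list of 27998 genes and the other 4 against a list of 32285 genes, which is the technical batch seen in the files.

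Perivascular cells were nearly undetected at E10.5 and made up more of the mesenchyme at later stages. Among mesenchymal cells (fibroblast-like, airway smooth muscle-like and perivascular), E10.5 A held 0 perivascular cells of 306, which allows a share of up to 0.98%, and E10.5 B held 2 of 1287 (0.155%, exact binomial 95% interval 0.019 to 0.56). The share was 1.11% in E12.5 A (16 of 1442 cells, 0.636 to 1.80) and 1.04% in E12.5 B (37 of 3568, 0.731 to 1.43). It was 5.37% at E14.5 (216 of 4020, 4.70 to 6.12), 10.4% at E16.5 (254 of 2448, 9.20 to 11.7) and 16.6% at E18.5 (72 of 435, 13.2 to 20.4). As a share of all cells used, it was 4.15% at E14.5, 8.15% at E16.5 (7.21 to 9.16) and 4.35% at E18.5 (3.42 to 5.44), so that the last step went down, while fibroblast-like cells were 56.4% of all cells at E16.5 and 17.7% at E18.5. Intervals and upper limits cover counting error only. The cluster was led by Cox4i2, a hypoxia-responsive subunit of cytochrome oxidase found in mural cells, by the transcription factor Ebf1, and by Pdgfrb, the receptor through which endothelial PDGF-B recruits pericytes. It also held the vascular smooth muscle cells. Ndufa4l2, another of its leading genes, itself changed with day, so the cells were also clustered with the markers of pericytes and smooth muscle left out. The shares were then 0% and 0.155% at E10.5, 0.661% and 0.654% at E12.5, 4.73% at E14.5, 7.72% at E16.5 and 15.2% at E18.5.

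The share of perivascular cells among mesenchymal cells rose with day over the 7 libraries (Pearson's r = 0.97, exact permutation p = 0.0008, two-sided, the smallest that these libraries can give, and Spearman's rho = 0.982, exact permutation p = 0.0016). This was the single relation tested in its family. Without E16.5 and E18.5, the 2 libraries farthest from the median day, r was 0.916 (exact permutation p = 0.0333) and rho was 0.949 (exact permutation p = 0.0667, the smallest that those 5 libraries can give for rho). With a stricter cell filter (at least 1000 genes and at most 5% mitochondrial UMIs per cell) r was 0.703 (exact permutation p = 0.0722), and with double the clustering resolution r was 0.72 (exact permutation p = 0.0579). In both settings vascular smooth muscle-like cells formed a cluster of their own, and with them counted in, r was 0.925 and 0.967 (exact permutation p = 0.0008 for each). The batches held 3 and 4 libraries, too few for a correlation. The shares in order of day were 0%, 1.11% and 5.37% with the shorter gene list and 0.155%, 1.04%, 10.4% and 16.6% with the longer one.

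**Figure D1:**
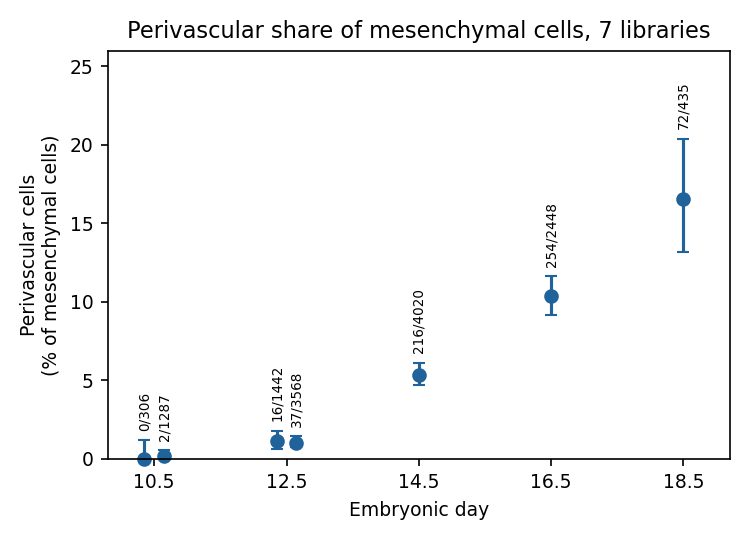
Share of perivascular cells among mesenchymal cells (vertical axis, percent) by embryonic day (horizontal axis), with 1 point per library, an exact binomial 95% interval as the bar, and the number of perivascular and of mesenchymal cells beside each point. The share lay between 0% and 0.155% at E10.5, at 1.04% and 1.11% at E12.5 and at 16.6% at E18.5.

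Marker-positive cells were also counted at a fixed depth, each mesenchymal cell being thinned to 4000 UMIs. This count does not use the perivascular cluster, but the mesenchymal class was itself named from clusters. At least 5 of 16 pericyte markers were then detected in 0.351% of cells in E10.5 A, 0% in E10.5 B, 1.17% in E12.5 A, 1.59% in E12.5 B, 5.05% at E14.5, 8.88% at E16.5 and 23.9% at E18.5. Cells with fewer UMIs were left out, so that 285, 1170, 1363, 2901, 3784, 2410 and 347 cells stood behind these shares, in the same order. Without thinning the shares were 22.2%, 4.20%, 19.3%, 7.71%, 12.1%, 15.9% and 30.3%, at median depths of 25769, 10851, 15768, 7830, 8839, 9561 and 5778 UMIs. In thinned epithelial cells, which should lack these genes, the share was between 0% and 0.658%.

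Within perivascular cells, 9 of 25 genes of fibrillar collagen and elastic matrix and 4 of 16 contractile genes rose between E12.5 and E18.5. Of 16 genes of DNA methylation and early chromatin 2 fell, and of 21 imprinted and fetal growth genes 2 fell, with Hmga2 in both lists. No list was called with an estimated correlation (lowest adjusted p = 0.301 with an estimated correlation). Mustn1, a small nuclear protein of muscle cells, rose the most among well-measured genes (log2 change per day 2.28, SE 0.18, adjusted p = 0.00857), from a normalised level of 0 CPM (the count scaled to a common library total) at E12.5 B to 1.44, 6.65 and 332 CPM at the later stages. The elastin gene Eln rose from 168 CPM through 882 and 2384 to 12560 CPM (1.00 per day, SE 0.06, adjusted p = 0.00349). Hmga2, a chromatin protein of fetal growth, fell from 350 CPM through 49.4 and 6.30 to 0 CPM (-1.47 per day, SE 0.09, adjusted p = 0.00349). The trend rested on summed counts of 4 libraries with at least 20 perivascular cells (E12.5 B, E14.5, E16.5 and E18.5, 1 per stage, n = 4). Changes can also follow the share of vascular smooth muscle cells in the class.

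Of 9789 genes tested, 335 changed with day by edgeR's quasi-likelihood test, two-sided, 292 rising and 43 falling. DESeq2 called 531, of which 364 rose (68.5% against 87.2% with edgeR). Without a count filter 1560 were called (1026 rising and 534 falling), and with E12.5 A admitted by a minimum of 10 cells, an alternative chosen after the data were seen, 1258 (770 rising and 488 falling). With the gene list as a covariate, which sets E14.5 against the other 3 libraries, 83 genes were called, 81 of them rising. Without E14.5, which leaves the 3 libraries of the longer gene list, 1 gene was called, Sftpc, and without E18.5 194 genes were. At E18.5 the stricter cell filter left 5 cells in the class and 25 in a vascular smooth muscle-like cluster. That filter called 271 genes over 3 libraries, with slopes to E16.5. Of 261 of the 335 genes tested there, 73 were also called and 22 had the opposite sign. Of the called genes named for this trend, 24 of 51 tested lost their call without E12.5 B, 38 of 39 without E14.5, 24 of 49 without E18.5 and 0 of 35 without E16.5.

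Among the other genes with the largest rises were Ramp1, a receptor activity-modifying protein (log2 change per day 1.51, SE 0.20, adjusted p = 0.0201), the caveolar protein gene Cav2 (1.36, SE 0.14, adjusted p = 0.011), Tinagl1, which encodes a matricellular protein (1.53, SE 0.20, adjusted p = 0.0193), and Fabp4, a fatty acid binding protein of capillaries and fat cells (1.29, SE 0.19, adjusted p = 0.026). Without E18.5 the changes of Ramp1, Cav2 and Fabp4 were 0.52, 0.87 and 0.44 (adjusted p = 0.281, 0.135 and 0.144). Sftpc, the surfactant protein C gene of type 2 alveolar epithelium, also rose (1.62, SE 0.24, adjusted p = 0.0273). Of its 1599 UMIs at E18.5, 1532 lay in 1 of the 72 cells. Without E18.5 the call ended under the main filter (0.57, adjusted p = 0.203) and the stricter (0.49, adjusted p = 0.379). The falling genes after Hmga2 were Phgdh, the first enzyme of serine synthesis (-0.53, SE 0.09, adjusted p = 0.0321), the nucleoside diphosphate kinase gene Nme1 (-0.47, SE 0.08, adjusted p = 0.0339), Srm, the spermidine synthase gene (-0.47, SE 0.08, adjusted p = 0.037), the beta-tubulin gene Tubb2b (-0.46, SE 0.08, adjusted p = 0.0341) and Rpf2, a ribosome production factor (-0.45, SE 0.09, adjusted p = 0.0479). Without E18.5 the adjusted p was 0.0514 for Nme1 and 0.0793 for Rpf2, and without E12.5 B it was 0.0701 for Rpf2.

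Of 22 pericyte genes tested, 3 rose and none fell, and 9 rose when adjusted over the list alone. Notch3, the Notch receptor of mural cells, rose from 83.9 to 398 CPM (log2 change per day 0.39, SE 0.07, adjusted p = 0.0343), and so did the periostin gene Postn (0.54, SE 0.05, adjusted p = 0.00906) and Ndufa4l2, a mitochondrial protein induced by hypoxia (0.78, SE 0.10, adjusted p = 0.0175). Without E18.5 Notch3 was at 0.25 per day (adjusted p = 0.188), and with the gene list as a covariate at 0.36 (adjusted p = 0.102). Pdgfrb did not pass the test (0.09, SE 0.06, adjusted p = 0.422), with 352, 263, 473 and 439 CPM from E12.5 to E18.5. The same held for Cspg4, the NG2 proteoglycan gene (0.35, SE 0.08, adjusted p = 0.0723). Nor did the G protein regulator gene Rgs5 (0.10, SE 0.09, adjusted p = 0.548) or the mural potassium channel genes Kcnj8 and Abcc9 (adjusted p = 0.753 and 0.665) pass. Under the stricter cell filter, up to E16.5, Rgs5 fell (-0.40, adjusted p = 0.0105) and Abcc9 rose (0.45, adjusted p = 0.00444). The pericyte list rose by camera (adjusted p = 7.34e-06). It did not with the correlation between genes estimated from the data (adjusted p = 0.301 with an estimated correlation). Of 26 lists tested in perivascular cells 15 were called with the preset correlation, 11 rising and 4 falling, and 0 with an estimated one.

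Of 16 contractile smooth muscle genes tested, 4 rose, and 8 rose when adjusted over the list alone (list adjusted p = 3.25e-07, and adjusted p = 0.392 with an estimated correlation). They were Mylk, the myosin light chain kinase gene (log2 change per day 0.52, SE 0.05, adjusted p = 0.011), the actin-binding protein genes Synpo2 (1.05, SE 0.15, adjusted p = 0.026) and Smtn (0.35, SE 0.06, adjusted p = 0.0329), and Myocd, the coactivator that switches on smooth muscle genes (0.81, SE 0.16, adjusted p = 0.0474). Myh11, the smooth muscle myosin heavy chain gene, stood at 71.3, 47.6, 134 and 1298 CPM and just missed the threshold (0.76, SE 0.16, adjusted p = 0.054). It passed without E12.5 B (1.19, adjusted p = 0.0328), without E16.5 (0.79, adjusted p = 0.00768) and under the stricter cell filter (0.34, adjusted p = 0.0459). Without E18.5 the adjusted p was 0.357 for Synpo2, 0.0883 for Smtn and 0.682 for Myocd, and without E12.5 B it was 0.0615 for Smtn. Acta2, smooth muscle actin (0.22, SE 0.08, adjusted p = 0.169), and Tagln (0.23, SE 0.12, adjusted p = 0.295) did not pass. In the vascular smooth muscle-like cells of the class alone, the median change of 15 contractile genes was 0.20 per day, against 0.26 in the class. Of the 15 slopes 12 were positive, and Mylk (0.47), Smtn (0.41), Des (0.68), Lmod1 (0.67) and Myocd (0.61) passed there (edgeR adjusted p = 0.0121, 0.0322, 0.0126, 0.0445 and 0.0471). The class held 4.65, 3.69, 1.12 and 0.32 UMIs of Actg2, the visceral smooth muscle actin, per UMI of Myh11 from E12.5 B to E18.5, and airway smooth muscle-like cells held 0.842, 0.75, 0.419 and 0.383.

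Of 25 genes of fibrillar collagen and elastic matrix, 9 rose, 13 when adjusted over the list alone (list adjusted p = 1.94e-12, and adjusted p = 0.301 with an estimated correlation). Besides Eln these included the proteoglycan gene Bgn (log2 change per day 0.42, SE 0.05, adjusted p = 0.015), the elastin cross-linking enzyme Loxl1 (0.59, SE 0.07, adjusted p = 0.0175) and the collagen gene Col1a1 (0.37, SE 0.06, adjusted p = 0.0295). Of 14 basement membrane genes 6 rose, 12 when adjusted over the list alone (list adjusted p = 4.65e-09, and adjusted p = 0.301 with an estimated correlation). Examples are Col4a1, a chain of type IV collagen, with 396 CPM at E12.5 B and 1749 CPM at E18.5 (0.38, SE 0.05, adjusted p = 0.0211), and the perlecan gene Hspg2 (0.62, SE 0.11, adjusted p = 0.0375). Of 19 BMP and TGF-beta signalling genes 4 rose, 9 when adjusted over the list alone (list adjusted p = 0.000267, and adjusted p = 0.301 with an estimated correlation). They were the TGF-beta binding protein gene Ltbp2, the receptor gene Tgfbr2 (0.47, SE 0.07, adjusted p = 0.0295) and the inhibitory SMAD genes Smad6 and Smad7 (0.62 and 0.34 per day). Without E14.5 the adjusted p of Eln was 0.0565 and that of Col4a1 0.182. Without E12.5 B it was 0.0544 for Bgn, 0.0915 for Col1a1, 0.0645 for Col4a1 and 0.0766 for Tgfbr2, and without E18.5 it was 0.346 for Hspg2, while neither Smad6 nor Smad7 passed without one or the other library.

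The lists that fell held few called genes. Of 28 cell cycle genes 1 fell, Rrm2, the ribonucleotide reductase subunit gene (log2 change per day -0.44, SE 0.08, adjusted p = 0.0472), and 14 fell when adjusted over the list alone (list adjusted p = 1.79e-10, and adjusted p = 0.424 with an estimated correlation). The proliferation marker Mki67 did not pass (-0.07, adjusted p = 0.621). Without E12.5 B and without E18.5, Rrm2 (adjusted p = 0.0891 and 0.0754) and Igf2bp1 (0.104 and 0.0616) did not pass. Of 21 imprinted and fetal growth genes 2 fell, Hmga2 and the RNA-binding protein gene Igf2bp1 (-0.41, SE 0.07, adjusted p = 0.0382). Adjusted over the list alone 7 fell and 1 rose (list adjusted p = 0.000267, and adjusted p = 0.301 with an estimated correlation). The growth factor gene Igf2 (0.03, adjusted p = 0.929) and the imprinted non-coding RNA gene H19 (0.22, adjusted p = 0.221) did not pass, but under the stricter cell filter Igf2 fell (-0.54, adjusted p = 0.000216). Of 16 genes of DNA methylation and early chromatin 2 fell, Hmga2 and the transcription factor gene Sox11, and the same number when adjusted over the list alone (list adjusted p = 5.74e-05, and adjusted p = 0.301 with an estimated correlation). None of 19 oxidative phosphorylation genes was called, and 3 fell when adjusted over the list alone (list adjusted p = 0.0482, and adjusted p = 0.467 with an estimated correlation).

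Markers of other cells and of handling moved with these groups. Of 17 genes of dissociation stress, which respond within minutes to tissue handling, 6 rose, 12 when adjusted over the list alone, with 1 falling (list adjusted p = 1.26e-08, and adjusted p = 0.416 with an estimated correlation). Junb rose from 12.6 to 739 CPM (log2 change per day 0.86, SE 0.09, adjusted p = 0.0139) and Btg2 from 46.1 to 1229 CPM (0.82, SE 0.12, adjusted p = 0.026). Of 8 interferon response genes 2 rose, Ifitm3 (0.50, SE 0.06, adjusted p = 0.0175) and Bst2 (0.79, adjusted p = 0.0315), and 5 when adjusted over the list alone (list adjusted p = 0.000267, and adjusted p = 0.301 with an estimated correlation). Of 11 capillary endothelium genes 2 rose, the connexin gene Gja4 (1.04, SE 0.10, adjusted p = 0.011), which mural cells also express, and Emp2 (0.48, SE 0.06, adjusted p = 0.0175), the same number when adjusted over the list alone (list adjusted p = 0.00414, and adjusted p = 0.301 with an estimated correlation). Of 3 alveolar epithelium genes tested 2 rose, Sftpc and Emp2, the same number when adjusted over the list alone (list adjusted p = 0.000505, and adjusted p = 0.301 with an estimated correlation). None of 5 erythroid genes was called, and 2 rose when adjusted over the list alone (list adjusted p = 0.0206, and adjusted p = 0.467 with an estimated correlation). Of 3 epithelial and 3 endothelial markers, 1 each rose, Sftpc and Esam, an adhesion molecule of endothelium (list adjusted p = 0.0335 and 0.0639, and adjusted p = 0.363 and 0.392 with an estimated correlation).

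The remaining lists were not called in perivascular cells. None of 8 Hedgehog response genes passed (list adjusted p = 0.603), nor did any of 8 retinoic acid signalling genes (list adjusted p = 0.468). Of 14 Wnt signalling genes Dkk3 rose (log2 change per day 0.55, SE 0.09, adjusted p = 0.0343) and Dkk2 fell (-0.62, SE 0.11, adjusted p = 0.0362). The median change was 0.02 while the test pointed down (list adjusted p = 0.409). Of 24 lung mesenchyme transcription factors Gata6 alone rose (0.55, SE 0.09, adjusted p = 0.0352), the median being 0.01 while the test pointed down (list adjusted p = 0.727). Tbx4 (0.17, adjusted p = 0.182), Tbx5 (-0.05, adjusted p = 0.718), Foxf1 (adjusted p = 0.995), Tcf21 (adjusted p = 0.339), the Hedgehog target Gli1 (adjusted p = 0.756) and Pdgfra (adjusted p = 0.553) did not pass, and Wt1 was below the count filter. Under the stricter cell filter Foxf1 (0.48, adjusted p = 0.0107) and Tbx4 (0.44, adjusted p = 0.0185) rose and Pdgfra fell (-0.48, adjusted p = 0.00678). Of 9 Notch genes only Notch3 rose (list adjusted p = 0.138), and of 17 vascular growth genes only Pdgfa (0.44, SE 0.09, adjusted p = 0.0476, list adjusted p = 0.188). Of 18 glycolysis and hypoxia genes Egln3 and Pfkp rose (list adjusted p = 0.207), and of 11 myofibroblast and lipofibroblast genes Limch1 (list adjusted p = 0.908). Of 10 distal tip genes Clu rose and Mycn fell (list adjusted p = 0.737). Adjusted over the list alone, 2 Notch, 3 glycolysis and hypoxia and 2 distal tip genes rose, and the other counts of these lists were the same. None of the 4 sex check genes passed (list adjusted p = 0.727). Of these genes Dkk3, Gata6, Pdgfa, Pfkp and Clu lost their call both without E12.5 B and without E18.5, Dkk2 without E12.5 B, and Limch1 without E18.5. Under the stricter cell filter the signs of Myocd (-0.09) and Smad6 (-0.01) were opposite without passing, and Gata6 fell (-0.53, adjusted p = 0.000604). The cell cycle, early chromatin and BMP and TGF-beta lists were not called under that filter.

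**Figure D2:**
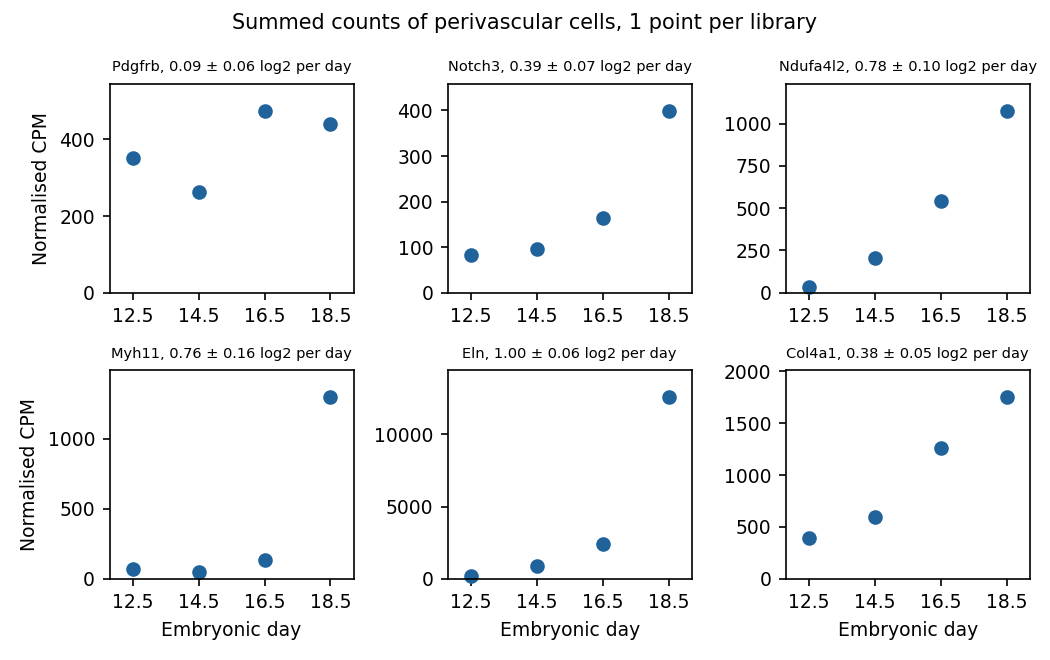
Normalised CPM of Pdgfrb, Notch3, Ndufa4l2, Myh11, Eln and Col4a1 in perivascular cells (vertical axes, linear from 0) by embryonic day (horizontal axes), with 1 point per library and the log2 change per day with its standard error above each panel. Eln reached 12560 CPM at E18.5, while Pdgfrb lay between 263 and 473 CPM.

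Whole mesenchyme, summed over all mesenchymal cells of a library, was tested over all 7 libraries, since it does not depend on how mesenchymal cells were divided among themselves. It does depend on which cells were named mesenchymal. E10.5 mesenchyme held 306 and 1287 cells, and 125 and 904 under the stricter cell filter, where 161 and 320 E10.5 cells were named cardiomyocyte-like. Fmo2, a flavin monooxygenase, rose from at most 0.124 CPM in the 4 libraries of E10.5 and E12.5 to 6.46, 96.9 and 998 CPM (log2 change per day 2.08, SE 0.11, adjusted p = 5.3e-05). Dpt, the dermatopontin gene of adventitial fibroblasts, reached 289 CPM (1.89, SE 0.08, adjusted p = 4.2e-05). Hmga2 fell from 1087 and 1058 CPM at E10.5 to 1.03 CPM at E18.5 (-1.34, SE 0.13, adjusted p = 0.000446). Isl1, a transcription factor of early foregut and heart mesoderm, fell from 86.6 and 102 CPM to 0.342 CPM (-1.14, SE 0.10, adjusted p = 0.000302). Crabp2, a retinoic acid binding protein, fell from 139 and 173 CPM to 1.03 CPM (-0.98, SE 0.06, adjusted p = 9.71e-05). Of 14482 genes tested by edgeR, two-sided, 6106 changed with day, 3292 rising and 2814 falling. Within the longer gene list 1682 genes were called and within the shorter one 381, and the stricter cell filter called 5168. Most mesenchymal cells of each stage sat in clusters of their own. Dpt and Clec3b, a tetranectin gene that also rose (1.62, SE 0.15, adjusted p = 0.000333), were leading genes of the E18.5 cluster.

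The pericyte genes rose in whole mesenchyme, where the share of perivascular cells also rose. Of 23 tested 18 rose, 20 when adjusted over the list alone (list adjusted p = 2.2e-11, and adjusted p = 0.0772 with an estimated correlation). Pdgfrb rose from 32.4 and 41.2 CPM at E10.5 to 173 CPM at E18.5 (log2 change per day 0.25, SE 0.03, adjusted p = 0.000944), Cspg4 from 1.60 to 70.8 CPM (0.62, SE 0.04, adjusted p = 0.000119). Abcc9 (0.90, SE 0.10, adjusted p = 0.000776), Kcnj8 (0.52, SE 0.08, adjusted p = 0.00223) and Notch3 (0.18, SE 0.05, adjusted p = 0.0207) rose as well. Notch3 was at 0.04 without E18.5 (adjusted p = 0.372) and at -0.01 within the shorter gene list. Rgs5 did not pass (0.13, SE 0.06, adjusted p = 0.115), but did without the 5% of cells with the highest doublet scores (0.15, adjusted p = 0.0462). Of 18 contractile genes 13 rose, 15 when adjusted over the list alone (list adjusted p = 8.38e-07, and adjusted p = 0.272 with an estimated correlation), with Tagln at 0.64 per day (SE 0.09, adjusted p = 0.00142). Acta2 (0.71, SE 0.26, adjusted p = 0.0597) and Myh11 (0.75, SE 0.32, adjusted p = 0.091) did not pass over the whole range, but Acta2 did under the stricter cell filter (0.69, adjusted p = 0.0317). Airway smooth muscle-like cells were not detected at E10.5, so changes of contractile genes can also follow that class.

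Most matrix genes rose. Of 25 genes of fibrillar collagen and elastic matrix 23 rose, 24 when adjusted over the list alone (list adjusted p = 2.74e-20, and adjusted p = 0.0772 with an estimated correlation). Mfap4, a microfibril protein, rose from 105 CPM in E10.5 A to 3356 CPM at E18.5 (log2 change per day 0.68, SE 0.03, adjusted p = 4.82e-05), and Col3a1 from 197 to 5040 CPM (0.54, adjusted p = 8.66e-05). Of 16 basement membrane genes 12 rose, 13 when adjusted over the list alone (list adjusted p = 1.62e-10, and adjusted p = 0.199 with an estimated correlation), among them Col4a2 (0.60, adjusted p = 6.37e-05). Of 15 myofibroblast and lipofibroblast genes 12 rose, 13 when adjusted over the list alone (list adjusted p = 1.6e-06, and adjusted p = 0.0772 with an estimated correlation), including Tcf21, the transcription factor of lipofibroblasts (0.45, SE 0.05, adjusted p = 0.000818), Pdgfra (0.26, adjusted p = 0.00122) and the carboxylesterase gene Ces1d (0.90, adjusted p = 4.25e-05). Of 22 BMP and TGF-beta genes 10 rose and 3 fell, the same adjusted over the list alone (list adjusted p = 0.0245, and adjusted p = 0.392 with an estimated correlation). Of 10 Notch genes 6 rose and 1 fell, the same adjusted over the list alone (list adjusted p = 0.0131, and adjusted p = 0.369 with an estimated correlation). Of 23 vascular growth genes 12 rose, 13 when adjusted over the list alone (list adjusted p = 0.00345, and adjusted p = 0.224 with an estimated correlation).

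Of 28 cell cycle genes 6 fell in whole mesenchyme and none did when adjusted over the list alone (list adjusted p = 1.15e-05, and adjusted p = 0.49 with an estimated correlation), Rrm2 with a log2 change per day of -0.35 (adjusted p = 0.00947). Mki67 did not pass (adjusted p = 0.718), but rose without E18.5 (0.12, adjusted p = 0.0447). Of 16 DNA methylation and early chromatin genes 6 fell and 1 rose, 7 and 1 when adjusted over the list alone (list adjusted p = 0.000309, and adjusted p = 0.224 with an estimated correlation), with Sox11 at -0.43 and the DNA methyltransferase gene Dnmt3b at -0.19 per day. Of 19 oxidative phosphorylation genes 8 fell, the same adjusted over the list alone (list adjusted p = 0.00345, and adjusted p = 0.51 with an estimated correlation). Members of several lists went both ways without a call for the list. Of 10 Hedgehog genes 2 rose, with Hhip, the Hedgehog-binding protein gene, at 0.42 per day (0.24 without E18.5, adjusted p = 0.213), and 2 fell, with Foxf1, a Hedgehog target in lung mesenchyme, at -0.22 (adjusted p = 0.00458). The list was not called (adjusted p = 0.652). Of 20 Wnt genes 4 rose and 5 fell (list adjusted p = 0.828), and of 14 retinoic acid genes 3 rose and 3 fell (0.172). Of 27 lung mesenchyme transcription factors 7 rose and 6 fell (0.866), of 23 imprinted and fetal growth genes 6 rose and 9 fell (0.0755), and of 21 glycolysis genes 4 rose and 9 fell (0.157). The median was -0.01 for the Wnt genes, whose test pointed up, and 0.02 for the transcription factors, whose test pointed down. Adjusted over the list alone 5 Wnt genes rose and 7 fell, 5 retinoic acid genes fell, 5 glycolysis genes rose, and the other counts were the same. Examples are Stra6, the retinol transporter gene (-0.84, adjusted p = 0.000128), the RNA-binding protein gene Lin28b (-1.70, adjusted p = 0.000105) and the pyruvate kinase gene Pkm (-0.38, adjusted p = 0.000214), which fell. Wif1, a secreted Wnt inhibitor gene (0.92), and Tbx4 (0.28, adjusted p = 0.00155) rose. Tbx5 (adjusted p = 0.256), Gli1 (0.36), Igf2 (0.302) and H19 (0.628) did not pass.

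Genes of other cell types moved in whole mesenchyme too. Of 9 erythroid genes 6 rose and 1 fell, the same adjusted over the list alone (list adjusted p = 0.0344, and adjusted p = 0.49 with an estimated correlation), Hbb-bs reaching 927 CPM (log2 change per day 1.78, SE 0.32, adjusted p = 0.0045). Of 7 leukocyte genes 5 rose, the same adjusted over the list alone (list adjusted p = 0.0077, and adjusted p = 0.243 with an estimated correlation). Of 15 alveolar epithelium genes 10 rose, with 1 falling when adjusted over the list alone (list adjusted p = 0.00131, and adjusted p = 0.49 with an estimated correlation), Sftpc reaching 640 CPM (1.46, adjusted p = 0.00129). Of 9 proximal airway genes 5 rose, the same adjusted over the list alone (list adjusted p = 0.032, and adjusted p = 0.49 with an estimated correlation). Of 17 capillary genes 7 rose and 1 fell, 8 and 1 when adjusted over the list alone (list adjusted p = 0.000605, and adjusted p = 0.0772 with an estimated correlation). Of 17 stress genes 11 rose and 1 fell, 11 and 2 when adjusted over the list alone (list adjusted p = 0.00345, and adjusted p = 0.419 with an estimated correlation), Junb rising from 11.4 to 474 CPM (0.64, adjusted p = 0.000275). Of 16 interferon genes 15 rose, 16 when adjusted over the list alone (list adjusted p = 1.15e-05, and adjusted p = 0.419 with an estimated correlation). Lists without a call were the epithelial markers (2 of 8 rose and 2 fell, list adjusted p = 0.828) and the endothelial markers (4 of 8 rose, 0.0881). So were the mesothelial markers (3 of 6 fell, 0.0654, with Wt1 at -0.94 per day, SE 0.16, adjusted p = 0.00325, but -0.46 with adjusted p = 0.119 under the stricter cell filter) and the distal tip genes (3 of 11 fell, 0.137). Adjusted over the list alone these counts were the same. Of 4 sex check genes Ddx3y rose (0.10, adjusted p = 0.00744, list adjusted p = 0.369).

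E12.5 against E10.5 was the comparison with replicates at both stages (2 libraries against 2). In whole mesenchyme Acta2 was at 5.66 and 22.1 CPM in the E10.5 libraries and at 482 and 671 CPM at E12.5 (log2 fold change 5.36, SE 0.69, adjusted p = 0.0197). The smooth muscle gamma-actin gene Actg2 was at 1.23 and 0.70 against 84.1 and 114 CPM (6.72, SE 0.33, adjusted p = 0.006), and Myh11 at 0 and 0.0636 against 78.7 and 126 CPM (adjusted p = 0.006). Nfix, a transcription factor gene, was also higher (6.23, SE 0.84, adjusted p = 0.0216). Lower at E12.5 were Wnt4 (42.0 and 122 against 2.07 and 2.12 CPM, -5.29, SE 0.59, adjusted p = 0.0156) and the chemokine gene Cxcl13 (335 and 256 against 11.96 and 16.9 CPM, -4.36, SE 0.25, adjusted p = 0.00606). So were the atrial myosin light chain gene Myl7 (-4.95, SE 0.58, adjusted p = 0.0168) and the keratin gene Krt18 (-4.46, SE 0.57, adjusted p = 0.0197). Wnt4 and Cxcl13 were leading genes of the cluster that held the E10.5 mesenchyme.

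By edgeR, two-sided, 944 of 13669 genes differed between E12.5 and E10.5, 521 higher and 423 lower at E12.5. Over all 13669 genes the change from E10.5 A to E12.5 A correlated at 0.771 with that from E10.5 B to E12.5 B, which are also the pairs within each gene list batch. No test is possible within a batch, which holds 1 library per stage. With the batch, which is also the letter, as a term in the fit 3077 genes were called. Leaving out either E12.5 library left 188 genes called, and Nfix, Acta2, Wnt4, Myl7 and Krt18 then no longer passed, with log2 fold changes for Acta2 of 5.59 without E12.5 A and 5.10 without E12.5 B (adjusted p = 0.0506 and 0.0545). Acta2 also missed the threshold without the highest doublet scores (5.12, adjusted p = 0.0529). Under the stricter cell filter, with fewer E10.5 cells named mesenchymal, Myl7 was at -2.99 (adjusted p = 0.0105). In E10.5 mesenchyme, cells with Barx1, a transcription factor gene of stomach mesenchyme, held the lung mesenchyme gene Wnt2 less often than other cells. With each cell thinned to 4000 UMIs, Wnt2 was detected in 8.57% against 21.3% of cells in library B and in 4.26% against 25.6% in library A (odds ratios 0.347 and 0.13, two-sided Fisher's exact test, adjusted p = 0.00111 and 0.00254 over 32 pairs of gene and library). In perivascular cells no test of these stages was possible, with 0 and 2 cells at E10.5 against 16 and 37 at E12.5.

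Whether genes changed over time in perivascular cells otherwise than in the remaining mesenchyme was tested with both classes of the same 4 libraries. Over 11415 genes no difference in trend passed by edgeR, two-sided, with 1218 genes at an unadjusted p under 0.05, while DESeq2 called 63. The lowest adjusted p was 0.0923. Genes at that value were Notch3 (slope in perivascular cells minus slope in other mesenchyme, 0.43 log2 per day, SE 0.05), Gata6 (0.51, SE 0.06), Sftpc (1.16, SE 0.14), Limch1, a contractile regulator of stress fibres (-0.47, SE 0.05), and Fibin (-0.79, SE 0.10). The count was 350 without E16.5 and, without E18.5, 270 (445 with the stricter filter). Under that filter Gata6 was called with the opposite sign (-0.42, adjusted p = 0.000853).

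Seen as lists, matrix genes had the lower slope in perivascular cells and contractile genes the higher. Of 25 genes of fibrillar collagen and elastic matrix, 11 were lower when adjusted over the list alone (list adjusted p = 1.42e-14, and adjusted p = 0.493 with an estimated correlation). Bgn (-0.25, adjusted p = 0.167) and Col6a3 (-0.50, adjusted p = 0.273) did not pass over all genes. For the 15 myofibroblast and lipofibroblast genes it was 5 (list adjusted p = 9.77e-13, and adjusted p = 0.493 with an estimated correlation). For the 16 basement membrane genes 5 were lower and 2 higher (list adjusted p = 0.000177, and adjusted p = 0.493 with an estimated correlation). Contractile genes had 5 of 17 higher when adjusted over the list alone (list adjusted p = 0.000406, and adjusted p = 0.559 with an estimated correlation), with Myocd at 0.85 (adjusted p = 0.139) and Synpo2 at 0.85 (adjusted p = 0.134). The 28 cell cycle genes had none (list adjusted p = 8.36e-08 for a higher slope, and adjusted p = 0.559 with an estimated correlation). The 19 glycolysis and hypoxia genes had 2 (list adjusted p = 3.14e-05 for a higher slope, and adjusted p = 0.493 with an estimated correlation). Pericyte genes as a list did not differ (4 of 23 higher and 1 lower when adjusted over the list alone, list adjusted p = 0.894). Other-cell and handling markers went both ways, adjusted over the list alone. Higher were 4 of 5 epithelial markers and 6 of 15 alveolar genes, with 1 lower (list adjusted p = 0.00014 and 0.00309). So were 4 of 17 stress genes and 1 of 5 endothelial markers (list adjusted p = 0.00131 and 0.0283). Of 13 capillary genes 3 were lower (list adjusted p = 0.00926). All had adjusted p of 0.493 or 0.559 with an estimated correlation. The epithelial markers rest on few perivascular cells at E18.5. A cell held 1532 of 1599 UMIs of Sftpc and 4 of 7 of Epcam, others 10 of 11 of Krt18 and 6 of 9 of Nkx2-1. With the preset correlation 16 of 27 lists differed, 10 with the higher and 6 with the lower slope in perivascular cells, and with an estimated correlation 0 did (lowest adjusted p = 0.493).

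Endothelium, the tissue that perivascular cells cover, was compared over all 7 libraries. Blood and lymphatic endothelium were not separated. A cluster of 150 cells of low depth, with the lymphatic gene Ccl21a among its leading genes, supplied 72 of the 154 cells at E14.5 and 16 of the 27 in E12.5 A. Ace, the angiotensin-converting enzyme, rose from at most 2.03 CPM up to E12.5 to 5.30, 41.9 and 530 CPM (log2 change per day 1.44, SE 0.07, adjusted p = 7.14e-06). Gpihbp1, which holds lipoprotein lipase on capillaries, rose from 0 CPM in E10.5 A to 564 CPM (0.77, adjusted p = 0.000108). Glp1r, the glucagon-like peptide 1 receptor gene, reached 324 CPM (1.28, SE 0.12, adjusted p = 9.1e-05). Etv2, the transcription factor that specifies endothelium, was at 130 and 114 CPM at E10.5 and at 0 in the other 5 libraries (adjusted p = 2.61e-05). Hmga2 fell from 501 and 574 CPM to 7.58 CPM (-0.85, SE 0.06, adjusted p = 1.18e-05). Also falling was Peg10, an imprinted gene (-0.71, SE 0.05, adjusted p = 1.16e-05). By edgeR, two-sided, 2463 of 10484 genes changed, 1363 rising and 1100 falling. Of the called genes named for this trend, 37 of 87 tested lost their call without E18.5. The count was 626 without E18.5, 1562 without E10.5 A, 794 without both E10.5 libraries and 882 with the stricter cell filter, which left 5 libraries, and 1166 and 144 within the longer and the shorter gene list.

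Of 20 capillary genes 12 rose, 16 when adjusted over the list alone, with 1 falling (list adjusted p = 5.46e-10, and adjusted p = 0.172 with an estimated correlation). Of 22 vascular growth genes 8 rose and 1 fell, 12 and 2 when adjusted over the list alone (list adjusted p = 0.000117, and adjusted p = 0.286 with an estimated correlation), including the chemokine gene Cxcl12 (log2 change per day 0.73, adjusted p = 2.06e-05), the receptor gene Tie1 (0.29) and S1pr1, the sphingosine 1-phosphate receptor gene (0.32, and 0.19 without E18.5, adjusted p = 0.0722). Of 13 interferon genes 10 rose, the same adjusted over the list alone (list adjusted p = 1.97e-10, and adjusted p = 0.286 with an estimated correlation), with Isg15 at 1.26 and Ifitm3 at 0.52 per day. Of 8 endothelial markers 6 rose, 7 when adjusted over the list alone (list adjusted p = 0.000214, and adjusted p = 0.292 with an estimated correlation), Pecam1 at 0.34 (adjusted p = 0.00255). Of 23 collagen and elastic matrix genes 12 rose, 13 when adjusted over the list alone (list adjusted p = 7.67e-06, and adjusted p = 0.172 with an estimated correlation). Of 14 basement membrane genes 9 rose, the same adjusted over the list alone (list adjusted p = 0.000214, and adjusted p = 0.286 with an estimated correlation), Col4a1 at 0.31 (adjusted p = 0.0034). Of 20 imprinted and fetal growth genes 9 fell and 2 rose, 11 and 2 when adjusted over the list alone (list adjusted p = 1.75e-06, and adjusted p = 0.191 with an estimated correlation), among them Cdkn1c, a cell cycle inhibitor gene (-0.23, adjusted p = 0.000571). Of 28 cell cycle genes 6 fell, 9 when adjusted over the list alone (list adjusted p = 0.000117, and adjusted p = 0.531 with an estimated correlation). Of 20 glycolysis genes 9 fell and 4 rose, the same adjusted over the list alone (list adjusted p = 0.00378, and adjusted p = 0.462 with an estimated correlation), with the enolase gene Eno1 at -0.35 and Pgam1 at -0.34 per day. With the preset correlation 17 of 27 lists were called in endothelium, also including 3 lists of other cells given below, contractile genes (4 of 13 rose), Notch genes (4 of 11 rose), Wnt genes (4 of 11 fell and 1 rose), oxidative phosphorylation genes (3 of 19 fell) and early chromatin genes (3 of 16 fell and 1 rose), none of them with an estimated correlation.

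In the 150 endothelial cells at E18.5, 1 cell held 154 of 158 UMIs of Tagln, 150 of 153 of Acta2 and all 31 of Myh11. Of the matrix genes, 47.4% of Fbln5, 44.5% of Col5a2 and 35.2% of Mfap4 UMIs lay in 1 cell, and 16, 57 and 8 cells held a UMI of these genes.

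Genes of other cells rose in endothelium as well. Of 9 alveolar epithelium genes 7 rose, 8 when adjusted over the list alone (list adjusted p = 1.88e-05, and adjusted p = 0.292 with an estimated correlation). Sftpc stood at 3301 CPM at E18.5 and at most 30.7 CPM before (log2 change per day 1.86, SE 0.19, adjusted p = 0.000127), with 23.9% of its UMIs at E18.5 in 1 cell, and did not pass without E18.5 (0.99, adjusted p = 0.0882). Of 6 erythroid genes 4 rose, the same adjusted over the list alone (list adjusted p = 0.0056, and adjusted p = 0.388 with an estimated correlation), Hbb-bs reaching 2242 CPM (1.37, SE 0.22, adjusted p = 0.00191) with 56.7% of its UMIs in 1 cell. The stress list was not called in endothelium (5 of 16 rose and 1 fell, 7 and 1 when adjusted over the list alone, list adjusted p = 0.0757). All 3 leukocyte genes tested rose, over all genes and adjusted over the list alone (list adjusted p = 0.000226, and adjusted p = 0.286 with an estimated correlation), with 30 of 32 UMIs of Tyrobp and 14 of 21 of Fcer1g at E18.5 in 1 cell each.

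Epithelium, a lineage with known stage markers, was compared over the same 7 libraries. Sftpc rose from 13.3 and 0.885 CPM at E10.5 through 266 and 168 at E12.5, 1876 at E14.5 and 15460 at E16.5 to 163800 CPM at E18.5 (log2 change per day 1.73, SE 0.13, adjusted p = 9.85e-05). Lyz2, the lysozyme of type 2 cells, reached 6891 CPM (2.75, SE 0.12, adjusted p = 5.87e-06) and Retnla, a secreted resistin-like protein, 2241 CPM (3.06, SE 0.11, adjusted p = 7.25e-06). Scgb1a1, the secretoglobin of club cells, was at 0 in all libraries up to E14.5, at 23.3 CPM at E16.5 and at 16600 CPM at E18.5 (adjusted p = 5.87e-06). Isl1 (-1.27, SE 0.08, adjusted p = 4.91e-05), Igdcc3, a cell surface immunoglobulin gene (-1.20, SE 0.13, adjusted p = 0.000553), the glucose transporter gene Slc2a3 (-1.13, SE 0.16, adjusted p = 0.0022) and Crabp2 (-1.07, SE 0.09, adjusted p = 0.00018) fell. By edgeR, two-sided, 2448 of 12289 genes changed, 1641 rising and 807 falling (67% rising, against 56.3% with DESeq2). Of the called genes named for this trend, 25 of 76 tested lost their call without E18.5 and 22 of 83 without E10.5 B. The count was 963 without E18.5, 1611 with the gene list as a covariate, and 471 and 722 within the longer and the shorter gene list. Most of the 377 E18.5 cells of the class sat in a cluster of their own, led by Sftpc, Retnla and Slc34a2. A cluster of 194 cells, all from E18.5 and led by Ager and Hopx, genes of type 1 alveolar cells, was not in the class. With it kept 2646 genes were called, all 18 alveolar genes tested rose, and Shh did not pass (-0.16, adjusted p = 0.0863).

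Of 18 alveolar genes 15 rose, the same adjusted over the list alone (list adjusted p = 1.07e-22, and adjusted p = 0.203 with an estimated correlation), among them the protease gene Napsa (log2 change per day 2.17, adjusted p = 5.87e-06), the lamellar body gene Lamp3 (1.90) and Slc34a2, the phosphate transporter gene of type 2 cells (2.35, SE 0.26, adjusted p = 0.000708). Of 10 proximal airway genes 6 rose and 1 fell, 7 and 1 when adjusted over the list alone (list adjusted p = 8.06e-07, and adjusted p = 0.351 with an estimated correlation), with Scgb3a2 at 1.83 (adjusted p = 0.000137) and Cyp2f2, a cytochrome of club cells, at 1.49 per day. Without the 5% of cells with the highest doublet scores, the test of the proximal airway list called a fall (median -0.544, adjusted p = 0.0458). The 12 distal tip genes went both ways, 1 rising, the growth factor receptor gene Fgfr2 (0.16, adjusted p = 0.0127), and 2 falling, Mycn (-0.41) and the sonic hedgehog gene Shh (-0.21), with no call for the list (adjusted p = 0.953, the median being 0.04 while the test pointed down). Fgfr2 did not pass without E18.5, Shh without E18.5 or either E10.5 library, and Mycn without E10.5 B or either E12.5 library. Nkx2-1, the transcription factor of lung epithelium, rose (0.15, adjusted p = 0.0282), but not without E18.5 (adjusted p = 0.261), E10.5 A, E10.5 B or E12.5 A, with a change of -0.03 within the shorter gene list. Of 23 imprinted and fetal growth genes 9 fell and 3 rose, 11 and 3 when adjusted over the list alone (list adjusted p = 0.000499, and adjusted p = 0.265 with an estimated correlation). Hmga2 was at -0.58 (adjusted p = 0.00092), while Dlk1 rose to 6071 CPM (0.73, adjusted p = 0.000137).

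Of 11 retinoic acid genes 4 fell and 2 rose in epithelium, the same adjusted over the list alone (list adjusted p = 0.00382, and adjusted p = 0.265 with an estimated correlation), with Stra6 at -0.69 and the retinoic acid receptor gene Rarb at -0.29 log2 per day. Of 10 Hedgehog genes 3 fell, 5 when adjusted over the list alone (list adjusted p = 0.00149, and adjusted p = 0.523 with an estimated correlation). Of 25 lung mesenchyme transcription factors 6 fell, 7 when adjusted over the list alone, with 2 rising (list adjusted p = 0.00206, and adjusted p = 0.523 with an estimated correlation), Osr1 at -0.66. Of 16 DNA methylation and early chromatin genes 3 fell, the same adjusted over the list alone (list adjusted p = 0.00119, and adjusted p = 0.523 with an estimated correlation). None of 28 cell cycle genes was called, over all genes or adjusted over the list alone (list adjusted p = 8.86e-05 for a fall, and adjusted p = 0.587 with an estimated correlation). Within the shorter gene list the cell cycle list was called rising (median 0.104, adjusted p = 0.00182). Genes of other cells and of handling moved here too. Of 17 stress genes 5 rose, 11 when adjusted over the list alone, with 1 falling (list adjusted p = 0.000499, and adjusted p = 0.523 with an estimated correlation). Of 24 collagen and elastic matrix genes 7 rose and 2 fell, 11 and 2 when adjusted over the list alone (list adjusted p = 0.00729, and adjusted p = 0.523 with an estimated correlation). Of 6 leukocyte genes 3 rose, the same adjusted over the list alone (list adjusted p = 0.000499, and adjusted p = 0.265 with an estimated correlation), and of 7 endothelial markers 3 rose, 5 when adjusted over the list alone (list adjusted p = 0.00228, and adjusted p = 0.523 with an estimated correlation).

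Some of the genes that lead the comparisons lie as follows in the GRCm38 (mm10) mouse genome, each a protein-coding gene of the GENCODE M21 annotation, with the identifier of the files and the first and last base of the whole gene. Mustn1 (ENSMUSG00000042485) lies on chromosome 14 from 30879200 to 30881610, Eln (ENSMUSG00000029675) on chromosome 5 from 134702593 to 134747323, and Hmga2 (ENSMUSG00000056758) on chromosome 10 from 120361275 to 120476469. Notch3 (ENSMUSG00000038146) lies on chromosome 17 from 32120820 to 32166852, Pdgfrb (ENSMUSG00000024620) on chromosome 18 from 61045150 to 61085061, Cspg4 (ENSMUSG00000032911) on chromosome 9 from 56865033 to 56899870, and Ndufa4l2 (ENSMUSG00000040280) on chromosome 10 from 127514967 to 127517154. Myh11 (ENSMUSG00000018830) lies on chromosome 16 from 14194535 to 14291372, Acta2 (ENSMUSG00000035783) on chromosome 19 from 34241090 to 34255590, Actg2 (ENSMUSG00000059430) on chromosome 6 from 83512905 to 83536265, and Col4a1 (ENSMUSG00000031502) on chromosome 8 from 11198423 to 11312826. Isl1 (ENSMUSG00000042258) lies on chromosome 13 from 116298281 to 116309689, Ace (ENSMUSG00000020681) on chromosome 11 from 105967945 to 105989964, Etv2 (ENSMUSG00000006311) on chromosome 7 from 30633616 to 30635852, Sftpc (ENSMUSG00000022097) on chromosome 14 from 70520949 to 70524081, and Scgb1a1 (ENSMUSG00000024653) on chromosome 19 from 9083636 to 9087958.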

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

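The alternatives with at least 10 cells, the highest 5% of doublet scores removed, mural markers left out of clustering, both E10.5 libraries left out, the cluster led by Ager and Hopx kept in epithelium, a single gene list, the 2 farthest libraries left out and vascular smooth muscle-like cells counted in were chosen after the data were seen. All others were planned. Perivascular trend, 335 genes: stricter filter 271 (3 libraries, with 73 of 261 tested calls kept and 22 of opposite sign), DESeq2 531, no count filter 1560, gene list as a covariate 83, 0.375 as the resolution 115, at least 10 cells 1258, mural markers left out 73, leave-one-out 1 to 486. At double resolution no fit was possible. Whole mesenchyme, 6106: longer list 1682, shorter list 381 (4 and 3 libraries), leave-one-out 4202 to 5457. Endothelium, 2463: stricter filter 882, highest doublet scores removed 971, without both E10.5 libraries 794, longer list 1166, shorter list 144, leave-one-out 626 to 2684. Epithelium, 2448: cluster led by Ager and Hopx kept 2646, covariate 1611, longer list 471, shorter list 722, leave-one-out 963 to 2384. Calls had the opposite sign most often within the shorter list, 166 of 5747 tested in mesenchyme, 91 of 1539 in endothelium and 208 of 1915 in epithelium. Perivascular against other mesenchyme, 0: DESeq2 63, no filter 208, stricter filter 445, doublets kept 37, resolution 0.375 1, at least 10 cells 114, mural markers left out 57, leave-one-out 0 to 350. E12.5 against E10.5, 944: no filter 1560, leave-one-out 188 to 976. With the letter as a replicate block it was 3077. Only 2 pairs exist, so the letters are not shown to pair the libraries (deviations of same-letter libraries correlated at 0.594 across genes, and 1117 genes differed between letters with stage in the fit). Fewer libraries are tested when one is left out, and otherwise the cause was not tested. The perivascular comparison of E12.5 with E10.5 and its alternatives were not run, for want of cells.

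The perivascular share against day (r = 0.97, rho = 0.982) gave r = 0.703 and rho = 0.746 under the stricter filter (exact permutation p = 0.0722 and 0.0603) and r = 0.72 at double resolution (exact permutation p = 0.0579), since vascular smooth muscle-like cells left the class, and rho = 0.949 without the 2 farthest libraries (exact permutation p = 0.0667, the smallest that those 5 libraries can give, so this says nothing about stability). Leaving out 1 library gave r from 0.955 to 0.975 and rho from 0.971 to 0.986, and as a share of all non-erythroid cells r was 0.828 (exact permutation p = 0.0135). Of the gene lists called with the preset correlation (15, 18, 17, 12 and 16 in the perivascular, mesenchymal, endothelial and epithelial trends and the comparison of trends), 0 were called in any of the 5 with an estimated correlation.

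Of 1733 pairs of named gene and setting in the perivascular trend 1343 kept direction and call, 211 lost the call, 107 gained one and 8 were called on one side with opposite signs. In mesenchyme this was 2043, 163, 12 and 3 of 2232, in endothelium 1540, 236, 11 and 5 of 1802, in epithelium 1752, 232, 48 and 8 of 2052, in the comparison of trends 1229, 0, 203 and 8 of 1497, and for E12.5 against E10.5 85, 11, 0 and 0 of 96. Opposite signs arose, in log2 per day, under the stricter filter in perivascular cells for Rgs5 (-0.40), Foxf1 (0.48), Igf2 (-0.54), Myocd (-0.091), Smad6 (-0.012), Efnb2 (-0.46), Gata6 (-0.53) and Npnt (-0.46), which all passed the test there except Myocd and Smad6. In the comparison of trends they arose under that filter for Sfrp2 (-1.11), Gata6 (-0.42), Igf2 (-0.27), H19 (-0.31), Krt18 (-1.87) and Krt19 (-1.70), and Hba-x without E16.5 (4.50, leave-one-out -3.12 to 4.50) and Aldh1a2 without E18.5 (1.02, leave-one-out -0.85 to 1.02) turned, and all 8 passed there. In mesenchyme it was Notch3 in the shorter list (-0.012), Mki67 without E18.5 (0.12, leave-one-out -0.16 to 0.12) and Krt8 without both E10.5 libraries (0.056), of which Mki67 passed (adjusted p = 0.0447). In the shorter list alone it was, in endothelium, Foxf1 (-0.084), Rara (-0.053), Atp5g1 (0.0091), Cox5a (0.0085) and Ier3 (-0.045), none of them passing. In epithelium it was Lamb2 (-0.057), Col4a2 (-0.082), Ndufa1 (-0.035), Ces1d (-0.33), H2-K1 (-0.18) and Nkx2-1 (-0.029), of which Ces1d passed (adjusted p = 0.00135). Epithelial Nrarp turned under the stricter filter (-0.027) and without the highest doublet scores (-0.089). The lists called in the opposite direction were the cell cycle (median 0.104, epithelium, shorter list), proximal airway genes (-0.544, epithelium, highest doublet scores removed) and oxidative phosphorylation (-0.0326, comparison of trends, without E18.5, leave-one-out -0.0326 to 0.075). Of 2187 pairs of list and setting 1875 kept direction and call. The cause of these turns was not tested. Of the sums tested, the shallowest were E12.5 A endothelium (172134 UMIs) and E12.5 B perivascular cells (456108 UMIs).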

Other observations

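Tests chosen only after the result was seen were both tests of Sftpc, both tests of the other leading genes of airway smooth muscle, the count of called contractile genes in vascular smooth muscle-like cells alone, and the tests of embryo age, of Nkx6-1 and of Isl1. The spread asked of the vascular smooth muscle median was also set after that median was seen.

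Cell types outside the comparisons shifted as well (shares of all cells with exact binomial 95% intervals, 1 or 2 libraries per stage, no test made). Myeloid-like cells made up 25.95% of cells at E18.5 (430 of 1657, 23.9 to 28.1), against 7.54% at E16.5 (6.63 to 8.52), 3.48% at E14.5, and 0.929% (5 of 538) and 0% (0 of 1874, up to 0.16%) in the E10.5 libraries. Chondrocyte-like cells made up 6.49% (5.41 to 7.71) and 4.35% (3.79 to 4.96) of cells at E12.5, 2.77% at E14.5, 0% at E16.5 (up to 0.096%) and 0.543% at E18.5 (9 cells, 0.249 to 1.03). Airway smooth muscle-like cells, not detected at E10.5, made up 8.82% and 12.04% of cells in the E12.5 libraries.

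The E10.5 libraries held more neural-like and cardiomyocyte-like cells than later ones. Neural-like cells made up 4.46% (24 cells) and 8.22% (154 cells, 7.01 to 9.55) at E10.5 and at most 0.615% later, and cardiomyocyte-like cells 1.67% (9 cells) and 2.46% (46 cells, 1.80 to 3.26) at E10.5 and at most 0.27% later. The cardiomyocyte-like class depended on the processing. It held 161 and 320 E10.5 cells under the stricter cell filter and 94 and 483 with the highest 5% of doublet scores removed.

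Sftpc, a gene of type 2 epithelium, rose in perivascular cells. A candidate explanation is a droplet that held a perivascular and an epithelial cell, and 95.8% of the Sftpc UMIs at E18.5 lay in 1 cell of 72, which also held 82 UMIs of Sftpb, 87 of Sftpa1 and 97 of Cxcl15 beside 128 of Acta2. Free RNA may account for the rest, since without that cell Sftpc was at 110 CPM, 0.94 times the 117 CPM of fibroblast-like cells of the library. Both fit, for E18.5, and no biological explanation was tested.

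Of 16 contractile genes 4 rose in the perivascular class, and the list was called with a preset correlation but not with an estimated one (adjusted p = 0.392 with an estimated correlation). The test of airway smooth muscle cells set beforehand went with them. Actg2 per Myh11 UMI at E18.5 was 0.836 times that of airway cells. Tests made later argue against airway cells as the main source. Per library, 10 other leading genes had a median of at most 5.55% of the airway level, against 12.2% to 51.9% for contractile genes. At least 6 of 10 had an upper 95% Poisson bound under 0.5 times that contractile share (Enpp2 1.37% and Tgfbi 1.22% at E18.5). A smaller part stays open, since the upper bound of the median over genes exceeded that limit at E14.5 (6.15%) and E18.5 (58.0%). Of the 10, Ramp1 (215.27%), Tnnt2 (99.61%) and Lgr6 (45.97%) were high at E18.5. Leading genes first tried, at E18.5 alone, gave 2.03%. A growing share of vascular smooth muscle cells stays open for Mylk, Smtn and Myocd. Picked as called in the class, they rose in those cells too (edgeR adjusted p = 0.0121, 0.0322 and 0.0471). The cells tested were most of the class at E12.5 B and E18.5, so this cannot decide. For the 15 genes together a growing share and a change within the cells with age cannot be told apart, since their median in those cells, 0.201 against 0.261 in the class, has 95% bounds of 0.13 to 0.609 that reach below 0.131, the value that would have argued against it, and since the share depends on the processing (25 of 27, 105 of 214, 110 of 254 and 63 of 72 cells from E12.5 B to E18.5 at double resolution, but 25 of 30 at E18.5 and 0 before under the stricter filter).

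Foregut genes were present in mesenchyme at E10.5, where Barx1 stood at 76.2 and 84.0 CPM and Nkx6-1 at 64.1 and 89.3 CPM, and at most at 7.50 CPM at E12.5. For Barx1, cells of another tissue beside lung mesenchyme, such as stomach or oesophagus, may be included, as cells with Barx1 held Wnt2 less often (odds ratio 0.347, 0.172 to 0.643, in E10.5 B and 0.13, 0.015 to 0.522, in E10.5 A, Fisher's exact test, adjusted p = 0.00111 and 0.00254). Nkx6-1 showed no such pattern with Wnt2 (odds ratio 1.023 in E10.5 B, 0.73 to 1.42), and with Tbx5 its odds ratio was 2.40 in B and 0.829 in A, and Isl1 with Wnt2 gave 1.238 in B (0.883 to 1.72) and 0.582 in A (0.264 to 1.20), so for these 2 genes it stays open. The age of the embryos is another candidate explanation, and all 3 genes (Barx1, Nkx6-1 and Isl1) were lower in both E12.5 libraries, Isl1 without passing edgeR's test (log2 fold change -2.25, adjusted p = 0.0801). Age and the tissue taken cannot be told apart for the fall itself, since both follow the stage.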
